A study of Mus musculus with 9 samples.

How the data were processed

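RNA was sequenced from 9 libraries of mK4 cells, a mouse line derived from embryonic kidney mesenchyme, grown in medium with 10% serum. Per the labels, 5 libraries came from control cells that had received Cas9 with a non-targeting guide and 4 from clone F7, in which both copies of Foxd2 carry a frameshift. The extraction, library kit and sequencing layout are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical. Only 1 mutant clone was sequenced, so a difference between F7 and control can belong to the clone as well as to the genotype.

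Per the submitters' processing notes, reads were assigned to mm10 and counted with featureCounts, and DESeq2 1.18.1 was run in R 3.4.3. The aligner, the annotation and the use of strand are not given in the sources used here. The authors deposited a table of raw counts of reads per gene for 45808 gene symbols, and this was the input of every test. The authors' normalized table is a signal obtained by dividing each column of counts by a size factor. It was used only to check the raw table: within each library the ratio of raw to normalized values was constant. The authors' deposited comparison gives a log2 fold change and an adjusted p-value per gene, and its values are quoted only where that table is named. In each of the 2 per-library tables, 1 further F7 column matches no sample of the series and was not used, whereas the authors' own fit used all 10 columns. In the raw table, the headers of F7 replicate 3 and F7 replicate 4 read mk3 for the cell line, which differs from their sample titles. These columns were matched by clone and replicate number. Whether the label marks a different line or only a spelling was not tested.

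Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors) in R 4.3.3. Genes were kept by filterByExpr with its defaults, a minimum count of 10 in enough libraries for the smaller group and a total of at least 15, which left 14730 genes. The model held the group only. Adjusted p-values are Benjamini-Hochberg values over those genes, and a gene was called at an adjusted p under 0.05. The count of genes changed at least 2-fold also required an absolute log2 fold change of at least 1. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled by library total and TMM factor, as mean ± SD. Where a group held no read, the bound on the fold was computed against 3 counts over the whole group. Where it held 1 to 3 reads, the ratio is given with a 95% exact binomial interval. Such bounds and intervals cover counting error only.

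The 33 gene lists, the rule for named genes and the alternatives were written before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, voom values) at a preset correlation of 0.01 and adjusted over lists. An estimated correlation and fry, which tests a list by itself, were run beside it. Member counts are given over all genes and adjusted over the list alone. After the data were seen, an exact two-sided permutation test of each list's mean per library was added, over all 126 splits of the libraries into 5 and 4. It compares no list with other genes, and its smallest possible p is 0.00794. Each member was also left out of its list mean in turn. Named genes were Foxd2, its neighbour Foxd2os and Pax2; the 12 highest and 12 lowest log2 fold changes among called genes with a mean log2 CPM of at least 2 and no overlap between groups, leaving out symbols made of a clone or accession number; up to 3 members of each list with the smallest adjusted p; the highest and lowest fold of the authors' significant table; and each called member of the nephron progenitor, induced mesenchyme and renal stroma lists.

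Gene positions, types and transcript lengths came from the GENCODE annotation of the same build, matched by symbol for 93.9% of the tested genes. The alternatives were RLE and upper-quartile factors, no filter and a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out, an adjusted p under 0.01, a test against a fold of 2, and the authors' deposited table. Added after seeing the data were fits with parts of either group, a correction for transcript length, and counts without chromosome 8 alone and without chromosome 8 and 2 blocks of genes. These blocks are runs of windows of about 50 neighbouring tested genes whose absolute median log2 fold change reached that of the least shifted window of chromosome 8.

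The library totals ran from 6041556 to 16032175 counts. In counts simulated from these libraries, over 14526 genes, edgeR called 63.3% of genes changed 1.5-fold, 91.8% of those changed 2-fold, 93.8% of those changed 4-fold and 100% of those changed 8-fold. Of its calls, 5.03% were unchanged genes, against 8.95% for DESeq2 over 14730 genes. This was a single draw with 48 or 49 changed genes per fold for edgeR and 50 for DESeq2. It held no shift by chromosome or gene length, so these rates neither rank the methods nor give the error rate in the data.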

Results

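The transcriptome of mK4 cells was measured by RNA sequencing in control cells (n = 5) and in the Foxd2 mutant clone F7 (n = 4). Foxd2 encodes a forkhead transcription factor, and the series asks how its loss bears on renal hypoplasia and dysplasia. The 5 control libraries held 16032175, 13283785, 12296863, 10526591 and 11999321 counts. F7 replicates 1 and 2 held 14024859 and 11782243, whereas replicates 3 and 4 held 6041556 and 6590712 and so measured low genes less precisely. The first principal component carried 64.6% of the variance and parted the groups. Control replicates 3 and 5 lay nearest to F7 on it, at -19.2 and -25.3, where the other controls lay between -48.6 and -40.1 and the F7 libraries between 41.4 and 47.3. No replicate pair agreed within sampling noise.

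Foxd2 RNA was higher in the mutant, not lower. Foxd2 (ENSMUSG00000055210.4; mm10 chromosome 4, 114906282 to 114908873, minus strand) rose from 3.73 ± 0.538 CPM (SD, n = 5) to 18.3 ± 3.78 CPM (SD, n = 4), a log2 fold change of 2.30 (SE 0.16, edgeR adjusted p = 1.93e-07). The control libraries 1 to 5 measured 4.28, 3.19, 4.07, 3.99 and 3.12 CPM, and F7 libraries 1 to 4 measured 18.8, 23.32, 16.47 and 14.53 CPM. The neighbouring noncoding gene Foxd2os (114909257 to 114921967, plus strand) also rose, from 17.1 ± 2.41 to 42.4 ± 9.86 CPM (log2 fold change 1.32, SE 0.15, edgeR adjusted p = 2.91e-05). The annotated genes do not overlap, but the use of strand in the counting is not stated, so reads that extend past either gene cannot be assigned. Counts per gene do not show the frameshift or the protein, so this value does not check the genotype.

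Pax2, a transcription factor required for kidney formation and the gene the series' design names as changed, was lower in each F7 library than in each control. Pax2 (ENSMUSG00000004231.15; chromosome 19, 44756045 to 44837871, plus strand) fell from 153 ± 10.1 CPM (SD, n = 5) to 49.1 ± 2.38 CPM (SD, n = 4), a log2 fold change of -1.64 (SE 0.07, edgeR adjusted p = 1.82e-09). Pax2 lies in a block of 159 tested genes at the end of chromosome 19 that was lower in F7 as a whole (median log2 fold change -0.51, 88.7% of genes lower), and 7 of these genes had a lower value than Pax2. The authors' deposited table gave -1.61 for Pax2 and 2.21 for Foxd2.

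**Figure D1:**
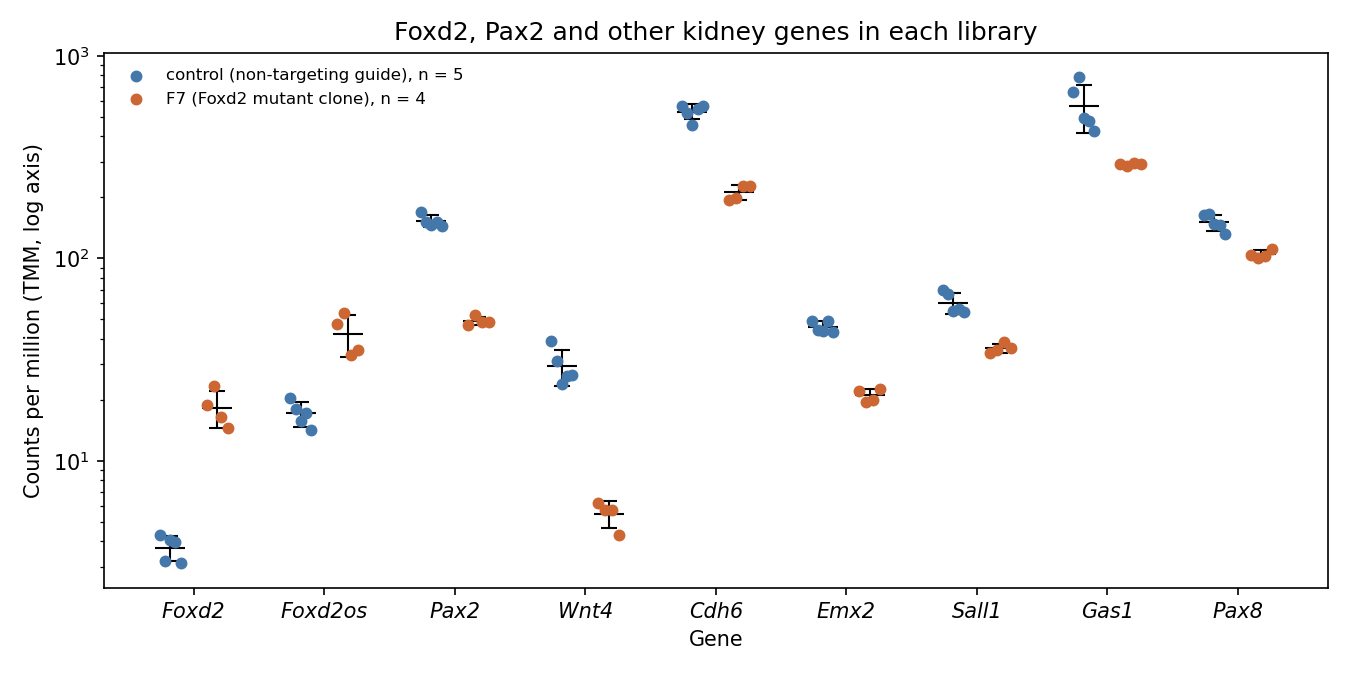
CPM (log axis) of 9 genes in each library, control (n = 5, blue) and F7 (n = 4, orange); bars are the mean ± SD. Foxd2 and Foxd2os lie higher in F7, and Pax2, Wnt4, Cdh6, Emx2, Sall1, Gas1 and Pax8 lie lower, with no overlap between the groups.

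Beyond these genes, 5196 of 14730 tested genes differed between F7 and control, 2561 higher and 2635 lower (edgeR, adjusted p under 0.05). A change of at least 2-fold was fitted for 1053 of them, 369 higher and 684 lower. A test against a fold of 2 itself called 365 genes, and with F7 replicates 3 and 4 as the only mutant libraries 2160 genes differed, against 4149 with F7 replicates 1 and 2. Several genes fell from clear expression to a small part of it, some to almost no reads. Igf2, a fetal growth factor, fell from 664 ± 57.7 to 11.17 ± 3.003 CPM (log2 fold change -5.95, SE 0.15, edgeR adjusted p = 9.72e-11). Igf2os fell with it (-5.87), but it overlaps Igf2 on the opposite strand, so their reads cannot be told apart. Abi3bp, a matrix-associated gene, fell from 488 ± 160 to 6.65 ± 2.87 CPM. The transcriptional regulator Setbp1 had 2420 reads in control and 2 in F7, a ratio of 707 after scaling (95% interval 195 to 5839). Fbln7 had no read in F7 and was at least 96.6-fold lower. Ston2, Krt15 and Dpysl5 had 1 read each in F7, and Ccser1, Cysltr1 and Dact1 were also among the lowest. In the other direction, Ptgs2, the inducible cyclooxygenase, rose from 0.0872 ± 0.0558 to 36.7 ± 19.6 CPM (log2 fold change 8.52, SE 0.64), and the transcription factor Nfia from 0.310 ± 0.234 to 51.5 ± 5.98 CPM (7.20, SE 0.21). Sash1 had 2 reads in control and 432 in F7, a ratio of 370 (95% interval 102 to 3064). Ptp4a3, the highest fold of the authors' deposited table, had no read in control and was at least 138-fold higher. The homeobox gene Rhox5 (5.10), the actin crosslinker Flnc (4.80), Dpep1 (4.66), Tbc1d9, Prkg2, Ccbe1, Eps8, the iron exporter Slc40a1 and Ccnd1 completed the 12 highest by log2 fold change among called genes with a mean log2 CPM of at least 2 and no overlap between groups.

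Several genes of the early nephron were lower in F7. Of 8 tested members of the nephron progenitor and metanephric mesenchyme list, 3 fell (Pax2; Sall1, log2 fold change -0.76; Gas1, -0.96), 1 rose (Eya4, 0.39) and 4 did not pass. Adjusted over the list alone, 3 fell and 2 rose. Of 15 tested genes of induced mesenchyme and early nephron, 6 fell and 2 rose, and adjusted over the list alone 7 fell and 2 rose. Wnt4, the signal that drives mesenchyme into epithelium, fell from 29.4 ± 5.92 to 5.49 ± 0.837 CPM (log2 fold change -2.40, SE 0.16, edgeR adjusted p = 2.65e-07). The cadherin Cdh6 (-1.32), the homeobox gene Emx2 (-1.12) and Pax8 (-0.52) also fell, with a smaller value for Irx2 (-0.21), whose call was lost in 13 of 21 other settings. Ccnd1, a cell cycle cyclin, rose from 10.9 ± 6.48 to 81.4 ± 32.2 CPM, and the Notch ligand Jag1 by 0.76 on the log2 scale, a call that was lost with F7 replicates 3 and 4 alone (edgeR adjusted p = 0.139). Camera did not call either list (adjusted p = 0.0764 and 0.0589), although the induced mesenchyme list passed in some other settings, as with F7 replicates 3 and 4 alone (0.0131) or without the low-count filter (0.0413). The mean of the progenitor list differed by -0.40 and that of the induced mesenchyme list by -0.31 on the log2 scale, both lower in all 4 F7 libraries than in all 5 controls (exact permutation adjusted p = 0.0262 for each). Pax2 and Emx2 lie in the block of chromosome 19 (median log2 fold change -0.51) and Sall1 on chromosome 8, where the median of the 731 tested genes was -0.35. Without the genes of these regions and of a higher block on chromosome 2, neither list mean passed (differences -0.14 and -0.25, exact permutation adjusted p = 0.179 and 0.0819), and the induced mesenchyme mean also did not pass without Wnt4 alone (unadjusted exact p = 0.103).

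Of 34 tested genes linked to human congenital anomalies of the kidney and urinary tract, 16 fell and 4 rose (camera adjusted p = 0.00448, lower). Adjusted over the list alone, 16 fell and 5 rose. The list call was lost with an estimated correlation (adjusted p = 0.538). The list mean lay lower in all 4 F7 libraries than in all 5 controls, by a difference of -0.51 (exact permutation adjusted p = 0.0262). Besides Pax2 and Wnt4, Fras1, whose product anchors epithelium to its basement membrane, fell from 154 ± 33.7 to 21.5 ± 3.56 CPM (log2 fold change -2.86, SE 0.19, edgeR adjusted p = 1.60e-06). Without the members on chromosome 8 or in the block of chromosome 19, Pax2 and Sall1 among them, 13 of 30 fell and 3 rose, and both tests still passed (camera adjusted p = 0.00727; exact permutation adjusted p = 0.0328). The list shares Pax2, Wnt4, Sall1 and other genes with the kidney lists and is not independent of them.

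Renal stroma genes moved in both directions, with 5 of 14 tested members higher and 5 lower (adjusted over the list alone, 5 and 6; camera adjusted p = 0.978). The cadherin Fat4 (log2 fold change 2.53), the Wnt antagonist Sfrp1 (1.69), the pericyte receptor Pdgfrb (1.24) and Ecm1 (0.56) rose, and Ecm1 lost its call with F7 replicates 3 and 4 alone (edgeR adjusted p = 0.113). Postn, a matrix protein, fell from 2469 ± 356 to 458 ± 148 CPM (log2 fold change -2.43, SE 0.20), and Meis2 (-1.04), Nr2f2 (-0.83) and Tbx18 (-0.41) fell as well. Decorin (Dcn) had 117 reads in control and 1 in F7, a ratio of 68.3 (95% interval 12.03 to 2722). Of 7 ureteric bud and collecting duct genes, 2 rose and 3 fell (adjusted over the list alone, 2 and 3; camera adjusted p = 0.716). Without the member on chromosome 8 the list mean was higher in F7 by 0.41 (exact permutation adjusted p = 0.0437), against 0.04 with all members (0.704). That member, the epithelial cadherin Cdh16, fell by 2.18 on the log2 scale, Trps1 fell by 0.55, and Wnt11 rose from 0.419 ± 0.159 to 2.004 ± 0.295 CPM. Among 5 tubule genes, the water channel Aqp1 (-1.49) and the endocytic receptor Lrp2 (-1.12) fell and Atp1b1 measured -0.14 without a call (adjusted over the list alone, 2 fell; camera adjusted p = 0.0764). Among 6 podocyte genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.484), and both calls, Actn4 (0.18) and Podxl (-0.19), were lost in 10 and 13 of the 21 other settings.

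Cholesterol synthesis genes rose together in F7. All 24 members were called higher, also when adjusted over the list alone, with a median log2 fold change of 0.72 (camera adjusted p = 5.47e-19). This was the only list whose camera call held with an estimated correlation (adjusted p = 0.0459). Lanosterol synthase (Lss) rose from 72.8 ± 2.20 to 165 ± 15.6 CPM (log2 fold change 1.177, SE 0.07, edgeR adjusted p = 4.68e-08), the sterol demethylase Cyp51 by 0.98, and Hmgcs1, an early step of the pathway, by 0.92. The list mean rose by 0.75 (control SD 0.05, n = 5; F7 SD 0.04, n = 4; exact permutation adjusted p = 0.0262).

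Hypoxia and glycolysis genes rose as well, 19 of 26 being higher and 1 lower, and the same numbers adjusted over the list alone (median log2 fold change 0.60; camera adjusted p = 2.57e-06, but adjusted p = 0.477 with an estimated correlation). Hexokinase Hk2 (1.402), the prolyl hydroxylase Egln3 (1.19) and Ankrd37 (2.17) had the smallest adjusted p. Of 46 cytosolic ribosomal protein genes, 35 were higher and none was lower, and adjusted over the list alone 41 were higher (median 0.36; camera adjusted p = 9.00e-10, but adjusted p = 0.555 with an estimated correlation). Rpl35 rose by 0.59, Rps25 by 0.57 and Rpl23 by 0.46. These 3 calls were lost with F7 replicates 3 and 4 alone, and reads of this family can be shared with its many pseudogenes. Control replicates 3, 4 and 5 stood at 0.18, 0.09 and 0.20 on this list's mean and replicates 1 and 2 at -0.23 and -0.24, against 0.23 to 0.53 in F7. The ribosomal list missed the threshold by exact permutation (adjusted p = 0.0561), which the hypoxia and glycolysis list passed (0.0262). Short transcripts were higher in F7 in general (Spearman rho -0.24 between log2 fold change and length across 13830 genes, which are not independent replicates). With that trend removed, 22 ribosomal genes were called higher where 35 had been, with a median of 0.29. In the hypoxia and glycolysis list 19 genes were called higher, as before, with a median of 0.61.

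Collagen and extracellular matrix genes were mostly lower. Of 28 tested, 15 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.00448, but adjusted p = 0.477 with an estimated correlation). Besides Postn, Col6a2 fell from 294 ± 10.99 to 120 ± 16.5 CPM (log2 fold change -1.30, SE 0.08, edgeR adjusted p = 1.22e-07) and Col6a1 by 0.64 on the log2 scale. Of 19 HOX cluster genes, which pattern the body axis, 11 fell and 1 rose (adjusted over the list alone, 13 and 1; camera adjusted p = 0.00247, but adjusted p = 0.477 with an estimated correlation). All 19 were Hoxa or Hoxb genes, neighbours within their clusters, so they are not independent of each other. Hoxb8 (-0.68) and Hoxa10 (-0.75) fell, whereas Hoxb13 rose from 0.622 ± 0.329 to 4.48 ± 1.07 CPM. By exact permutation of the list means the adjusted p was 0.0262 for matrix genes and 0.0404 for HOX genes.

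The remaining 3 called lists varied more between the F7 libraries, and none passed by exact permutation of its list mean (adjusted p = 0.165, 0.115 and 0.0697 for FGF and ERK feedback, p53 targets and immediate early genes). Of 14 genes of FGF and ERK feedback, 7 rose, also when adjusted over the list alone, including Etv5 (log2 fold change 2.63), Il17rd (2.46) and Etv4 (2.07). The camera call (adjusted p = 0.00762) was lost with an estimated correlation (adjusted p = 0.555), with F7 replicates 3 and 4 alone (0.359) and without control replicates 3 and 5 (0.0698). The list mean of F7 replicates 1 and 2 lay 1.14 and 1.13 above control, and that of replicates 3 and 4 at 0.15 and -0.06. Of 20 p53 targets, 9 rose and 1 fell (adjusted over the list alone, 11 and 1), with the smallest adjusted p for Pmaip1 (1.47), Tnfrsf10b (0.84) and Bax (0.60). Its camera adjusted p was 0.00451, and it was lost with an estimated correlation (adjusted p = 0.555) and with F7 replicates 3 and 4 alone (0.132). Of 20 immediate early genes, which respond to stimulation within minutes, 6 fell and 2 rose (adjusted over the list alone, 9 and 2; camera adjusted p = 0.00247, but adjusted p = 0.604 with an estimated correlation). Fosb fell from 114 ± 76.5 to 8.38 ± 4.69 CPM, a call that was lost with F7 replicates 3 and 4 alone (edgeR adjusted p = 0.0600) although the log2 fold change was larger there (-4.53, against -3.67 with all libraries), Jund fell by 0.57 on the log2 scale and Maff rose by 0.88. The list mean was -0.59 and -0.54 in F7 replicates 1 and 2 and -1.83 and -2.24 in replicates 3 and 4, and with replicates 1 and 2 alone the camera call was lost (adjusted p = 0.0662).

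**Figure D2:**
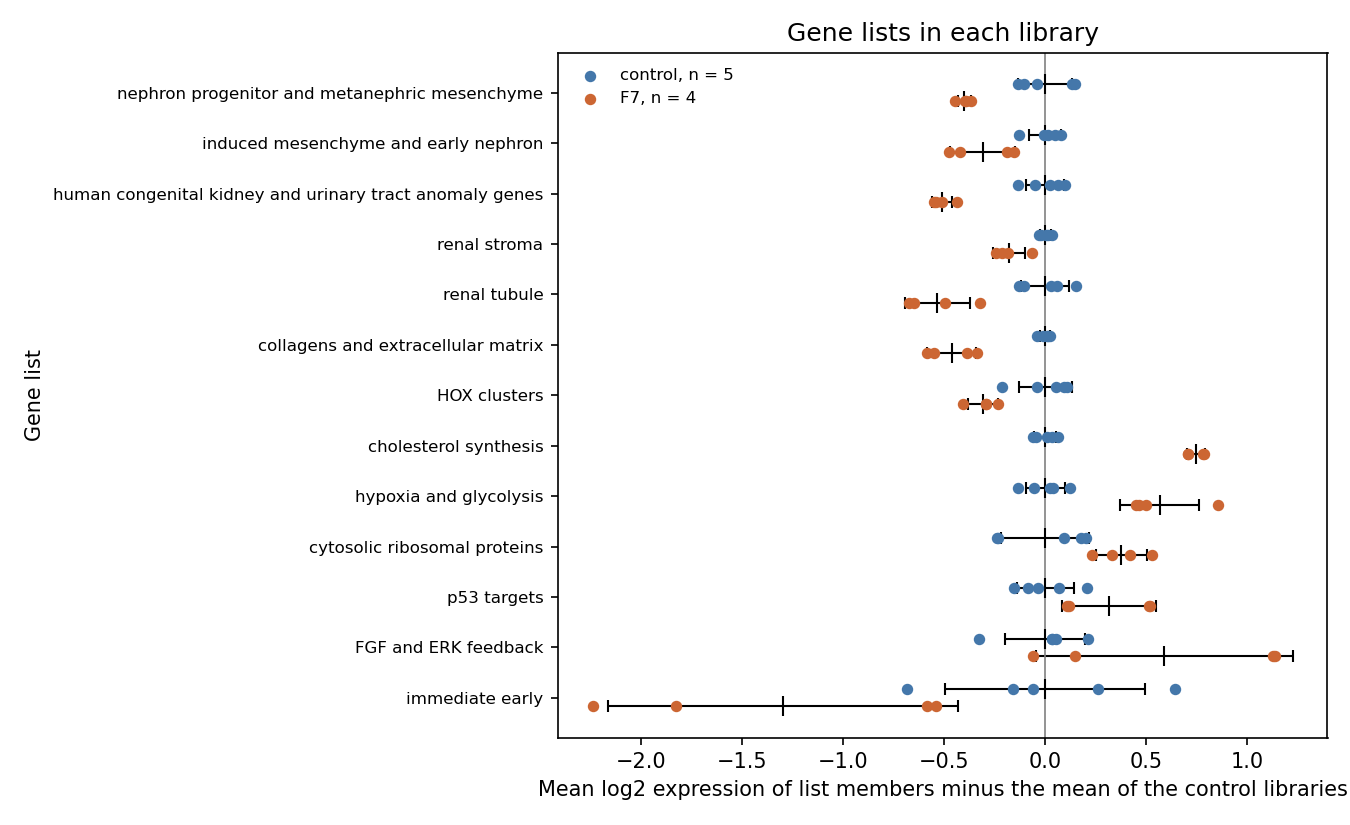
Mean log2 expression of the members of 13 gene lists in each library, relative to the mean of the control libraries, for control (n = 5, blue) and F7 (n = 4, orange); bars are the mean ± SD. Cholesterol synthesis lies between 0.71 and 0.79 in the F7 libraries, and the FGF and ERK, p53 and immediate early lists spread widely within F7.

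The other lists were not called by camera. In the cell cycle list 28 of 35 genes were not called, 3 rose, among them Aurka (log2 fold change 0.80), which lies in a block of 110 genes at the end of chromosome 2 with a median of 0.58, and 4 fell, among them Cdt1 (-0.50) and Mcm5 (-0.41), which lie on chromosome 8 (also adjusted over the list alone; camera adjusted p = 0.809). None of 13 mitochondrially encoded genes was called by edgeR or when adjusted over the list alone (camera adjusted p = 0.594). Of 21 interferon response genes 4 rose, among them H2-K1 (1.48) and H2-D1 (1.01), and 5 fell (adjusted over the list alone, 4 and 6; camera adjusted p = 0.809). Of 21 other FOX genes tested, 6 rose and 5 fell (adjusted over the list alone, 6 and 7; camera adjusted p = 0.996), with Foxa1 at -0.97, Foxf1 at 0.54 and Foxo6 at 0.95. Wnt targets included 3 higher genes, with Tcf7 at 1.38 and Dkk3 at 0.55, and 3 lower ones of 11 (adjusted over the list alone, 4 and 3; camera adjusted p = 0.404), Rnf43 having 164 reads in control and 1 in F7. BMP and TGF-beta targets had 3 higher, among them Pmepa1 (2.49), in the same block of chromosome 2, and Skil (0.83), and 3 lower, among them Smad9 (-1.21), of 14 (adjusted over the list alone, 4 and 3; camera adjusted p = 0.594). The Notch list had 1 higher and 1 lower gene of 11, Jag1 and Jag2 (-0.67), also adjusted over the list alone (camera adjusted p = 0.835). The retinoic acid list had 2 higher, Rdh10 (0.90) and Stra6 (0.34, its call lost in 6 of 21 other settings), and 1 lower, Rxra (-0.51), of 7, also adjusted over the list alone (camera adjusted p = 0.496). The stress response list had 9 higher, among them Ddit4 (1.28), and 2 lower of 26 (adjusted over the list alone, 9 and 3; camera adjusted p = 0.149). The mesenchymal list had 4 higher, among them Snai1 (1.77), Itgb3 (1.55) and S100a4 (1.77), and 1 lower of 13, also adjusted over the list alone (camera adjusted p = 0.219). The epithelial list had 2 higher, Cldn1 (0.74) and Jup (0.32), and 3 lower of 9, also adjusted over the list alone (camera adjusted p = 0.996).

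Markers of other cell types were few. None of 3 tested leukocyte genes was called over all genes or over the list alone, and their levels were low (Cd14 at 18.0 ± 6.91 CPM in control and 15.5 ± 1.77 CPM in F7). Of 4 endothelial genes 2 rose, Flt1, a VEGF receptor, from 10.5 ± 4.88 to 79.4 ± 13.1 CPM and Egfl7 by 0.93 on the log2 scale, also adjusted over the list alone. Of 5 skeletal muscle genes Tnnt2 (2.45) and Chrna1 (2.98) rose from low levels, also adjusted over the list alone (camera adjusted p = 0.0764). Of 4 smooth muscle genes 2 rose and Tpm1 fell by 0.35, of 6 cartilage and bone genes 1 fell (camera adjusted p = 0.809), and of 4 neuronal genes 3 rose, L1cam (0.44), Ncam1 (0.33) and Uchl1 (1.14), the last losing its call in 7 of 21 other settings. These 3 counts were the same adjusted over the list alone. Of 4 adipocyte genes 1 rose (Plin4, 1.37) and 1 fell, and adjusted over the list alone 2 rose and 1 fell. The lists with fewer than 5 tested members had no camera test. Among lists that camera did not call or test, exact permutation also passed for the means of the tubule (difference -0.54, adjusted p = 0.0262), endothelial (1.15, 0.0262), skeletal muscle (1.10, 0.0262), renal stroma (-0.18, 0.0262), neuronal (0.49, 0.0404) and mesenchymal (0.38, 0.0404) lists, besides the 2 early nephron lists. Some rest on single genes: without Postn the renal stroma difference was near 0 (unadjusted exact p = 0.992), and the skeletal muscle mean did not pass without Chrna1 (0.0635). Others kept their sign but shrank when 1 gene was left out. The smallest differences were 0.53 for the endothelial list (without Flt1), 0.23 for neuronal (Uchl1), -0.30 for tubule (Aqp1) and 0.26 for mesenchymal (S100a4). Median, mean and camera direction differed in sign for the ureteric bud, FOX, Wnt, BMP and TGF-beta, and cell cycle lists.

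The authors' deposited table held 1401 genes beyond 2-fold at an adjusted p under 0.05, 510 higher and 891 lower in F7. Of these, 976 were also among the 1053 genes called here, all 976 in the same direction. Of the other 425 genes, 348 had not passed the filter on low counts used here.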

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

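Among 272 sets of values, 1 for each named gene in each group plus the library totals and the chromosome 8 medians, 17 held a library that stood apart from the rest of its group, measured as its gap to the nearest library over the range of the group. Chance gives about 13.6 such cases. Control replicate 3 accounted for 6 of them. In control, it was highest for Rhox5 (5.48 CPM, next 1.94, ratio 0.735), Dpep1 (1.08 CPM, next 0.557, ratio 0.910) and Cdh16 (216 CPM, next 155, ratio 0.764). It was lowest for Cysltr1 (27.6 CPM, next 34.9, ratio 0.873), Atp1b1 (25.1 CPM, next 31.2, ratio 0.722) and Tnnt2 (0.415 CPM, next 1.21, ratio 0.718). Control replicate 1 was highest for Pax2 (170 CPM, next 152, ratio 0.716) and Nfia (0.724 CPM, next 0.253, ratio 0.844). Control replicate 5 was highest for Dpysl5 (13.4 CPM, next 10.96, ratio 0.727) and Itgb3 (3.29 CPM, next 2.04, ratio 0.727).

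In F7, replicate 4 was lowest for Hk2 (31.1 CPM, next 43.3, ratio 0.921) and highest for Eya4 (49.9 CPM, next 41.7, ratio 0.872). The 5 other cases in F7 were single reads where the remaining libraries had none, each with a ratio of 1: Ston2, Krt15 and Dpysl5 in replicate 2 (0.0857 CPM), Rnf43 in replicate 4 (0.153 CPM) and Dcn in replicate 3 (0.168 CPM).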

How the results depend on the processing

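The fits with parts of a group, the length correction and the counts without chromosome 8 or blocks were chosen after the result was seen. The calls and directions of Foxd2 and Pax2 held in all 21 other fits, and 100 of 120 called named genes kept their call in all of them. Among these, replicates 1 to 4 without the block and control replicate 5 left out hold the same libraries and are the same fit. A call lost or a direction turned there is counted under both names. RLE and upper-quartile factors moved no count of genes by over 1.5 times. Leaving out 1 library gave 3543 to 5872 changed genes (1709 to 2867 higher, 1834 to 3005 lower), 882 to 1213 changed at least 2-fold (334 to 408 higher, 537 to 805 lower) and 9 to 10 called lists. Without the low-count filter, which tests more genes, 1582 genes passed 2-fold (559 higher), and the median of all genes was -0.11. With F7 replicates 3 and 4 only, 2160 genes changed (988 higher, 1172 lower; 445 at least 2-fold lower), against 4149 with the deeper F7 replicates 1 and 2 only. With control replicates 1, 2 and 4 only, 1055 were at least 2-fold lower. The cause was not tested in either case. The stricter limit of 0.01 left 2894 genes (1363 higher, 1531 lower), and the test against a fold of 2 left 365 (159 higher, 206 lower). Without chromosome 8, 4704 genes changed, and without the blocks of chromosomes 2 and 19 as well 4510, with 10 called lists. Camera called induced mesenchyme in 7 other settings (adjusted p = 0.0413 unfiltered, 0.0492 with the block, 0.0131 with F7 replicates 3 and 4, and 0.0408, 0.0491, 0.0334 and 0.0398 with single libraries left out). It called renal tubule with F7 replicates 1 and 2 (0.0423) and without shifted regions (0.0487), skeletal muscle in 3 (0.0119, 0.0246 and 0.037) and the stress response list with F7 replicates 1 and 2 (0.0053). Camera with an estimated correlation called 1 list, and fry, which compares no list with other genes, called 16. The DESeq2 and limma voom alternatives were run for genes only. F7 replicates 3 and 4 are the shallowest libraries, and their raw headers read mk3 for the cell line. Their chromosome 8 medians (-0.32 and -0.34) lay near those of F7 replicates 1 and 2 (-0.37 and -0.36), with controls between -0.04 and 0.04. On this measure the libraries under both headers were alike, although the chromosome was picked over all F7 libraries together. How far depth or a difference behind this label bears on the calls was not tested.

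The replicate number as a block on replicates 1 to 4 gave 5082 changed genes and 1158 at least 2-fold, against 5373 and 1098 in the same 8 libraries without it. Deviations of same-numbered libraries correlated at -0.04, 0.07, 0.21 and -0.06, and only F7 replicate 3 correlated best with the control of its own number. This gave little sign of pairing by number, but so few pairs cannot exclude a shared culture or batch.

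No called list and no called gene among the 134 named ones changed direction. Uncalled ones did, the cause not being tested. By log2 fold change these were Plvap (-0.19 with F7 replicates 1 and 2), Cd14 (0.21 with control replicates 1, 2 and 4), Cd68 (-0.85 with F7 replicates 3 and 4), Csf1r (0.10 with the block, 0.083 without it, 0.045 with control replicates 1, 2 and 4), Tnnc1 (-0.070 with F7 replicates 3 and 4) and mt-Nd6 (-0.062 with the length correction). Over all single libraries left out the values were -0.019 to 0.46 for Plvap, -0.084 to 0.50 for Cd68 and -0.27 to 0.083 for Csf1r. By camera adjusted p, renal stroma turned without the filter (0.919), with replicates 1 to 4 unblocked (0.998), control replicates 1, 2 and 4 (0.985), the length correction (0.901), fry (0.0569) and some single libraries left out (0.807 to 0.998 over all 9). The FOX list turned with F7 replicates 1 and 2 (0.917), F7 replicates 3 and 4 (0.929), the length correction (0.595), fry (0.935) and 4 single libraries left out (0.887, 0.976, 0.976 and 0.949, and 0.807 to 0.998 over all 9). The epithelial list turned with the block (0.998), without it (0.976), with F7 replicates 1 and 2 (0.917), F7 replicates 3 and 4 (0.929), control replicates 1, 2 and 4 (0.876), the length correction (0.940), fry (0.479), no shifted regions (0.7099) and 4 single libraries left out (0.978, 0.976, 0.976 and 0.981, and 0.848 to 0.997 over all 9). Without those regions the ureteric bud (0.918) and BMP and TGF-beta (0.988) lists also turned. With F7 replicates 1 and 2 the Notch (0.917) and mitochondrial (0.8287) lists turned, and with F7 replicates 3 and 4 the BMP and TGF-beta (0.917), cell cycle (0.664) and interferon (0.526) lists. With the length correction the Notch (0.967), cell cycle (0.901) and mitochondrial (0.623) lists turned, and with fry the interferon list (0.646). Some single libraries left out also turned Notch (0.673 to 0.992 over all of them), interferon (0.751 to 0.992) and mitochondrial (0.107 to 0.852). The same holds, as camera adjusted p, cell cycle values running from 0.527 to 0.992, for that list.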

Other observations

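The tests on chromosome 8 and on blocks of genes, on gene length and on each list's mean per library were chosen after the result was seen, whereas the counts over other splits and the tests on neighbouring genes were set before. Some genes were read in 1 group and almost absent from the other. Taking a mean of at least 5 CPM in 1 group and at most 0.5 CPM in each library of the other, 10 genes were lost in F7 and 8 were gained. Beside genes already described, the lost genes included Vit (5.48 CPM in control) and Prkcdbp (6.33 CPM), and the gained genes included Pdzrn3 (9.25 CPM in F7), Megf10 (6.39 CPM), Mtm1 (5.16 CPM) and Fam198b (5.06 CPM), all chosen after their values were seen.

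By chromosome, random sets of genes put chromosomes 2, 8, 11, 15, 19 and X past an adjusted p of 0.05. Outside chromosome 8 the medians were 0.042, 0.092, 0.040, -0.096 and 0.046 in that order, but on chromosomes 19 and 2 these hide blocks shifted further than chromosome 8. From position 37376403 to the end of chromosome 19, 109 of 159 tested genes were called lower and 8 higher (median log2 fold change -0.51; F7 libraries -0.56 to -0.46, controls -0.01 to 0.01). From position 169633013 to the end of chromosome 2, 76 of 110 were called higher and 1 lower (median 0.58; F7 libraries 0.57 to 0.66, controls -0.04 to 0.05). The remaining windows off chromosome 8 were all shifted less than any window on it. The blocks were picked for their shift, so their windows cannot serve as a test of its origin, and none was made. In a simulation with chromosome 8 alone lowered, 2 other chromosomes passed as well, with medians up to 0.018 from that of all genes, so passing by itself says little. The medians given above lay further than that from the median of all genes here (-0.003). Among chromosomes without a block, chromosome 11 (0.092) lay furthest.

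Random assignment of these 9 libraries to groups rarely gave as many changed genes. The splits cannot show whether other clones or cultures would differ as much. Of 100 splits of the 9 libraries into 5 and 4, only the real one, 1 split, gave 5196 genes, and the highest other gave 4035. For the 2-fold count the real value was 1053, reached by 1 split, and the highest other was 814. The 2 splits with 4035 and 3286 genes set 4 controls against the rest and so keep most of the real grouping. Other splits of this kind gave 0 genes, so the count depended on which control was placed with F7. For the number of lists called by camera chance cannot be excluded, since 15 of the 100 splits, the real one among them, called 9 or more lists and the highest other called 13. Camera with a preset correlation therefore calls several lists in these libraries without the real grouping, so its calls are to be read with the tests of list means. Those tests in turn compare no list with other genes. Of all tested genes, 27.6% had no overlap between F7 and control, where chance gives 1.59%. A list mean can therefore pass without a change particular to that list.

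Genes of chromosome 8 were lower together in F7. The median log2 fold change of its 731 tested genes was -0.35, with 82.4% below 0, and it held 444 of the 2635 lower calls; the F7 libraries lay between -0.37 and -0.32 and the controls between -0.04 and 0.04. Gene length argues little for this, since the lowest median of 10000 random sets matched on length and expression was -0.025. The shift ran along the chromosome, 15 of 15 windows of about 50 genes having a median between -0.46 and -0.30, but the chromosome was picked for its shift, so this does not test its origin. Fewer copies of chromosome 8 in F7 than in control cells and an effect of Foxd2 loss cannot be told apart with 1 mutant clone and no DNA analysed here.

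Genes of the ribosomal protein list and of the hypoxia and glycolysis list were higher in F7 while short transcripts were higher in general. With the length trend removed, camera still called the ribosomal list (adjusted p = 2.43e-07, median 0.29 after and 0.36 before, SD 0.15 and 0.14). It also still called the hypoxia and glycolysis list (adjusted p = 4.31e-07, median 0.61 after and 0.60 before, SD 0.56 and 0.59). Without that correction both calls are lost with an estimated correlation (adjusted p = 0.555 and 0.477), and the ribosomal list misses by exact permutation (adjusted p = 0.0561). No list of 10000 matched on length and expression had a median as high as either, although matched lists for the ribosomal genes had a median of 0.16, so length may account for part of that shift. The spread of the ribosomal list between control libraries stays open as a source, as does Foxd2 loss, which cannot be told apart from the clone with 1 mutant clone.

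The genes lost or gained in F7 could mark deleted or gained regions. Taken as a set, their nearest tested neighbours within 500 kb argue against regions that reach those neighbours. The 16 neighbours of lost genes had a median log2 fold change of -0.037 (95% bootstrap interval -0.24 to 0.10). The 9 neighbours of gained genes had a median of 0.13 (-0.07 to 0.38). A median over all of them cannot exclude such a region at a single gene. Sash1, Prkcdbp and 2610305D13Rik had no such neighbour, and others, Setbp1 and Dact1 among them, had one on 1 side only. Igf2, itself strongly lower, was the only neighbour of a lost gene below -1, and Tmem144 (1.5) the only neighbour of a gained gene above 1. Changes within a single gene were not tested. Loss of Foxd2 and expression states fixed when the clone was founded cannot be told apart with 1 mutant clone.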
